A study of Mus musculus with 9 samples.

How the data were processed

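Biotin-labelled targets were hybridised to Affymetrix arrays, per the labels, with 3 arrays of adult mouse cornea, 2 of cornea at postnatal day 10, 2 of adult lens and 2 of adult flexor tendon. The deposited intensity values are a linear expression index per probe set. Per the series' design text, the authors used Microarray Suite 5.0 for absolute expression and detection calls and then dChip for invariant-set normalisation and a model-based index, while the processing notes in the labels name MAS5 without a version. Which program made the values is not given in the sources used here. Every array holds values below 0, which MAS5 signals do not. Detection calls were not used here, and no genome build is stated, so no coordinates are given.

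The table holds 12488 probe sets, of which 66 are controls. Of the 12422 others, 10833 carry 1 gene symbol, 396 carry several and 1193 none, and 10817 of the Entrez identifiers matched the reference gene table. The trimmed means of the arrays, over the values between percentiles 2 and 98, lay within a ratio of 1.171, under the limit of 1.25 set for keeping the values as deposited. Values at or below 0 were set to 0, a pseudocount of 16 was added and log2 was taken. Folds are therefore on the log2(value + 16) scale and understate differences of low genes. Control probe sets were left out of tests. A probe set was tested if it reached its array's median on at least 2 of the 9 arrays, which left 8154 probe sets, 7233 of them with 1 symbol, for 6109 genes. Of these, 87 had a value below -100 on some array.

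A group-means model was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean (5 residual and 4.933 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The number of arrays limits the precision, and a group of 2 arrays borrows its spread from the other groups. The adult cornea was compared with P10 cornea, lens and tendon, and the P10 cornea with lens and tendon. A probe set counted as shared by the cornea of both ages if it passed by at least 2-fold in the same direction in all 4 comparisons with lens and tendon.

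The lists cover small leucine-rich proteoglycans, collagens, collagen processing, basement membranes, matricellular genes, corneal soluble enzymes, epithelium, corneal endothelium, lens crystallins, lens fibres, tendon, skeletal muscle, adipocytes, red blood cells, leukocytes, melanocytes, vascular endothelium, Schwann cells, photoreceptors, cell cycle, antioxidant genes, antigen presentation, immediate-early genes, the respiratory chain, glycolysis, ribosomal proteins and growth factor signalling. Of 617 genes in the 27 lists 490 are on the array, 3 of them matched by an older symbol. Red blood cells had fewer than the 4 measured genes a test needed and have no result. Each gene was represented by its probe set with the highest mean. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 78 tests of 26 lists in the 3 comparisons of adult cornea, and 39 passed. Camera with an estimated correlation and fry were alternatives. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Some lists share genes: Fmod and Chad are in both the proteoglycan and tendon lists, Aldh3a1 and Aldh1a1 in the enzyme and antioxidant lists, Pax6 in the epithelial and lens lists and Eno3 in the muscle and glycolysis lists. The immediate-early list shares Klf4 with the epithelial, Egr2 with the Schwann cell and Ccn1 with the matricellular list. Tnc is in the matricellular and tendon lists.

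The comparisons, lists, tests, thresholds and the rule for named genes were set before the data were examined. The rule took, for each comparison of adult cornea, the 6 largest rises and the 6 largest falls of at least 2-fold among called probe sets with 1 symbol and no overlap between the groups. It added up to 3 called members of each list and always Kera, Lum, Dcn, Aldh3a1, Tkt, Krt12, Cryaa, Crybb2, Tnmd and Fmod. For the shared sets it took the 10 with the largest smallest fold. Of the genes the rule gave, those that matter most are named in the text.

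Alternatives covered pseudocounts of 1 and 64, filters on low values, quantile normalization, trimmed mean scaling, median centring, fits of only the groups compared, the test of the series' methods, a replicate block and leaving out each array. A further alternative, chosen after the data were seen, dropped probe sets with a value below -100. Exact tests were two-sided. On simulated data limma's test recovered 64%, 55% and 50% of 100 probe sets changed 2-fold in the comparisons of adult cornea with P10 cornea, lens and tendon, and 100%, 98% and 98% of those changed 4-fold, among 8154 probe sets. For P10 cornea against lens and tendon it recovered 40% and 36% at 2-fold and 96% and 98% at 4-fold. Between 4.09% and 5.63% of calls were false. Each simulation drew independent noise of equal spread in all groups and left 7954 probe sets unchanged. Differences between comparisons with the same numbers of arrays therefore come from the random draw. The recovered and false shares hold for these settings and need not hold for the measured data. Camera found all 9 shifted lists and called 2 of 69 unshifted ones among 6109 simulated genes. The simulated genes were drawn independently, whereas estimated correlations within the measured lists reached 0.818 for the lens crystallins. The simulation therefore does not show camera's error rate for correlated lists. Values were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.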

Results

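Gene expression was measured on 9 oligonucleotide arrays of the mouse genome, each hybridised with biotin-labelled RNA from 1 tissue preparation. The adult cornea, at 7 weeks of age, had 3 arrays, the cornea at postnatal day 10 (P10) had 2, the adult lens had 2 and an adult digital flexor tendon had 2. The corneas had been freed of limbus and scraped to remove most of the epithelium before extraction, so they were enriched for the stroma but kept some epithelial RNA. Replicates were independent RNA preparations, lens and tendon RNA came from pooled tissue, and p-values therefore measure the spread between preparations. The cornea arrays served an earlier study. In every comparison of cornea with lens or tendon, a batch therefore cannot be told apart from the tissue.

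All values below are deposited expression indices in arbitrary units, given as mean ± SD. The median index per array lay between 67.6 and 88.0 and the trimmed mean between 123 and 144, and the number of arrays limits the precision. Across tested probe sets, which are not independent replicates, log2 values correlated at r = 0.869 to 0.927 between adult corneas and at r = 0.866 to 0.902 between adult and P10 corneas. The replicates of tendon, P10 cornea and lens correlated at r = 0.978, 0.966 and 0.953. Adult corneas thus correlated less with each other than the replicates of the other groups did. The model assumed 1 spread per probe set for all groups, and the p-values for adult cornea rest on that assumption. Adult cornea correlated with lens at r = 0.398 to 0.519 and with tendon at r = 0.512 to 0.538. The Gapdh control had a 3'/5' ratio of 2.25 on adult cornea replicate 1, against 0.831 to 1.04 on the other arrays. The actin control had a ratio of 4.69 there against 1.07 to 2.07. Adult cornea replicate 1 thus stood apart from the other arrays in this measure of RNA quality.

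**Figure D1:**
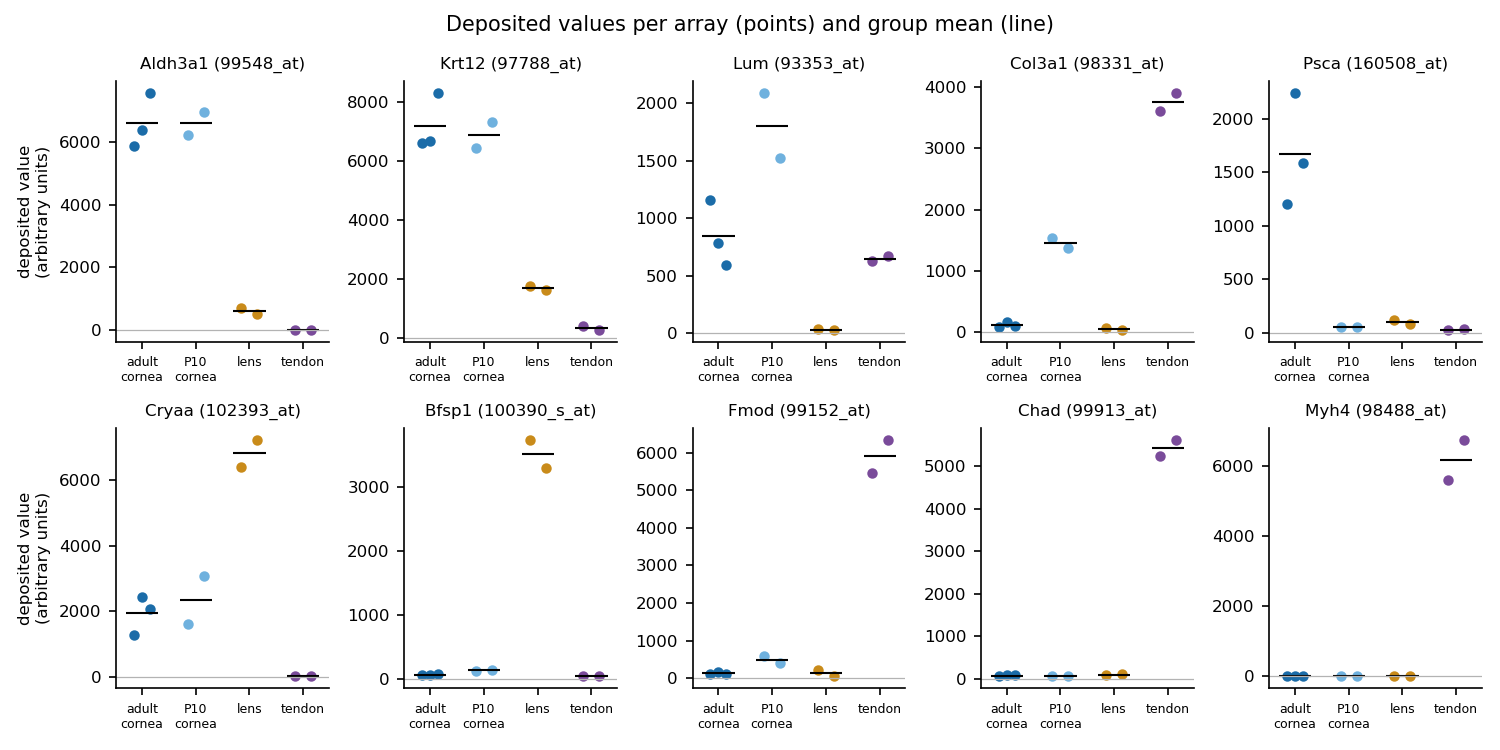
Deposited index (arbitrary units, linear axis) of 10 marker genes on each array; points are arrays, lines are group means, and the probe set stands beside each symbol. Aldh3a1 and Krt12 are high in cornea at both ages, Col3a1 is higher at P10 (1459) than in the adult (108), and Bfsp1, Chad and Myh4 mark lens, tendon and muscle.

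The comparison of adult with P10 cornea addressed how expression in the scraped cornea differs between the ages. The shares of stroma and of residual epithelium in the preparations were not tested. A difference in these shares between the ages cannot be told apart from a change within the cells. Genes of the collagenous matrix were lower in the adult. Of 14 fibril-forming and fibril-associated collagens, 11 fell and 0 rose (12 and 0 adjusted over the list alone). Col3a1, a fibril-forming collagen of young and loose connective tissue, fell from 1459 ± 111 (n = 2) at P10 to 108 ± 43.2 (n = 3) in the adult, 12.3-fold (log2 -3.62 ± 0.28 SE, limma adjusted p = 0.000163). Col5a2 and Col11a1, chains of minor fibrillar collagens that regulate fibril diameter, fell 6.40-fold (limma adjusted p = 0.000891) and 5.45-fold (limma adjusted p = 0.000491). The collagen list had a median log2 change of -1.46, or -1.33 relative to the median of all genes (camera in limma, adjusted p = 2.65e-13; adjusted p = 0.0413 with an estimated correlation).

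Other matrix groups were also lower in the adult cornea. Among basement membrane components 8 of 18 genes fell (11 adjusted over the list alone), including Col4a1 from 981 ± 26.7 (n = 2) to 209 ± 9.12 (n = 3; 4.43-fold, limma adjusted p = 0.000344) and Col15a1 from 105 ± 17.9 to 13.7 ± 4.65 (4.08-fold, limma adjusted p = 0.000548). Among 20 matrix remodelling and matricellular genes 7 fell and 0 rose (10 and 1 adjusted over the list alone). Eln, which encodes elastin, fell 4.67-fold (limma adjusted p = 0.000343), Thbs2 fell 4.07-fold (limma adjusted p = 0.000344), and Mfap2, a microfibril component, fell 3.55-fold (limma adjusted p = 0.000344). In collagen processing and crosslinking 5 of 12 genes fell (8 adjusted over the list alone), with Lox, a lysyl oxidase, 5.54-fold lower (limma adjusted p = 0.00372, but 0.0516 without P10 cornea replicate 1 and 0.122 with a pseudocount of 1). Median log2 changes relative to the median of all genes were -0.80, -0.62 and -0.70 for these 3 lists (camera in limma, adjusted p = 9.04e-10, 1.75e-05 and 2.33e-05; adjusted p = 0.159, 0.189 and 0.189 with an estimated correlation).

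Of 7 small leucine-rich proteoglycans, the collagen-binding proteoglycans that organise the stroma, 3 fell (6 adjusted over the list alone), with a median log2 change of -1.12, or -0.99 relative to all genes (camera in limma, adjusted p = 0.000208; adjusted p = 0.189 with an estimated correlation). Bgn, the biglycan gene, fell from 1442 ± 28.2 (n = 2) to 581 ± 138 (n = 3; 2.49-fold, limma adjusted p = 0.00808, but 0.0961 without P10 cornea replicate 1 and 0.0861 without replicate 2). Lum, which encodes lumican, fell from 1805 ± 398 to 845 ± 286 (2.17-fold, limma adjusted p = 0.0465). The Lum call was lost when any array except adult cornea replicate 1 was left out (limma adjusted p = 0.0675 to 0.432). It was also lost with trimmed mean scaling, median centring, a pseudocount of 1, a replicate block or a fit of only the groups compared (limma adjusted p = 0.0555 to 0.138). Kera was at 393 ± 67.8 at P10 and 213 ± 87.6 in the adult (limma adjusted p = 0.144). Dcn was at 4343 ± 365 and 2799 ± 275 (limma adjusted p = 0.106, 0.0299 with quantile normalization), and Fmod was at 492 ± 135 and 136 ± 37.2 (limma adjusted p = 0.0684, 0.0355 with a pseudocount of 64). Tnmd, a tendon gene, had no probe set assigned to it alone.

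**Figure D2:**
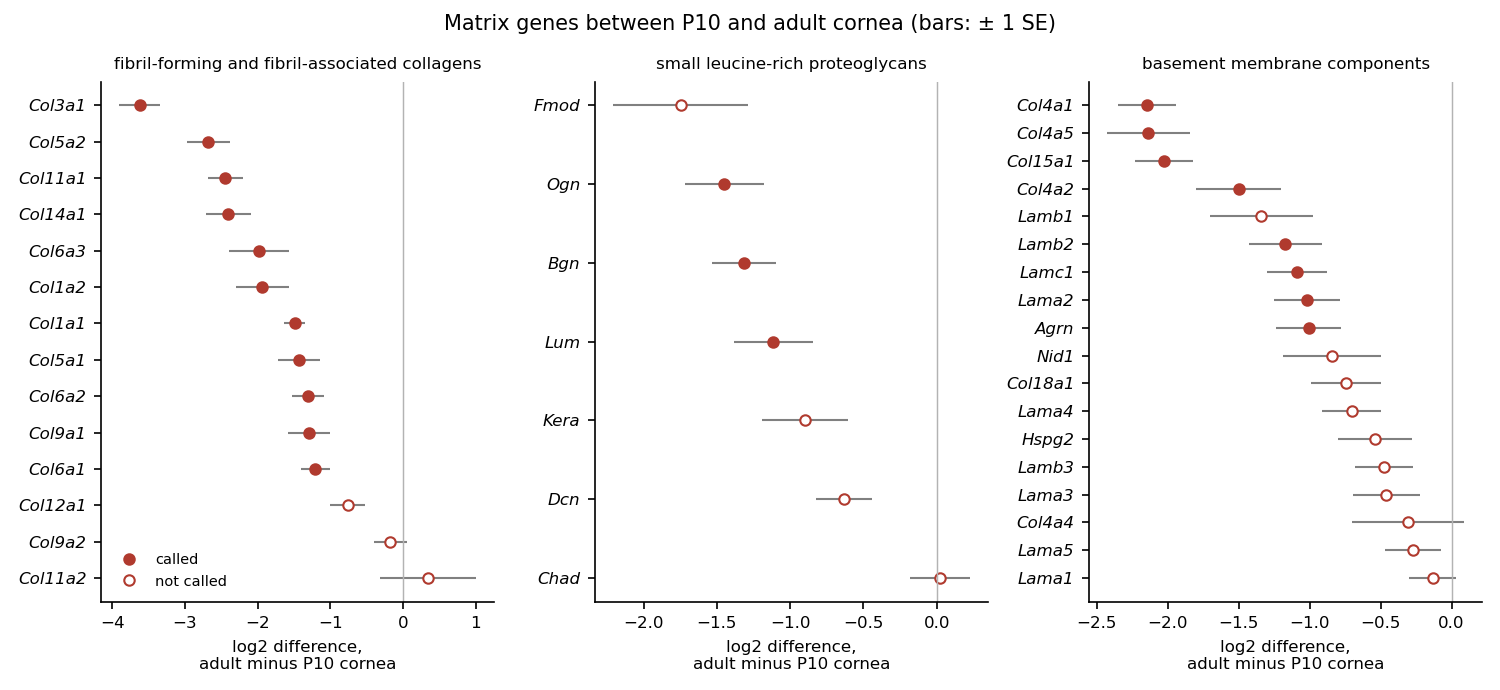
Log2 difference (adult minus P10 cornea, horizontal axis) of each measured gene of 3 matrix lists; points are estimates, bars are ± 1 SE, and filled points passed the adjusted test. Of the genes shown, 11 of 14 collagens, 3 of 7 proteoglycans and 8 of 18 basement membrane genes were lower in the adult, and the directions of the list medians held with quantile normalization and trimmed mean scaling.

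Several growth factor and cell type genes also changed with age. Igf2, a fetal growth factor, fell from 1103 ± 161 (n = 2) to 129 ± 25.6 (n = 3; 7.75-fold, limma adjusted p = 0.000293). Erbb4, a receptor tyrosine kinase, fell from 2276 ± 1.48 to 309 ± 190 (7.83-fold, limma adjusted p = 0.00181). Among 30 genes of Wnt, Fgf, Tgfb, Bmp and insulin-like growth factor signalling 4 fell and 0 rose (7 and 0 adjusted over the list alone; median log2 -0.28 relative to all genes; camera in limma, adjusted p = 0.00164; adjusted p = 0.377 with an estimated correlation). Igf2, Igfbp7 and Wnt6 were among the 4. In some settings calls were lost, as for Igfbp7 without adult cornea replicate 1 (limma adjusted p = 0.0607) and Wnt6 with quantile normalization (limma adjusted p = 0.0818). Col8a1, a collagen of the corneal endothelium's basement membrane, fell from 452 ± 21.0 to 72.6 ± 12.7 (5.31-fold, limma adjusted p = 0.000216) and was the 1 call among 4 endothelial genes (2 lower adjusted over the list alone; camera in limma, adjusted p = 0.00642; adjusted p = 0.231 with an estimated correlation). Ctsg, which encodes cathepsin G, was at 811 ± 19.7 at P10 and at -26.5 ± 73.1 in the adult (limma adjusted p = 5.43e-05). Dach1 was at 337 ± 65.7 and -10.3 ± 33.8 (limma adjusted p = 0.000293), and Icam5 fell 13.1-fold (limma adjusted p = 0.000344). Tendon arrays read above the P10 corneas for Erbb4 (3093 and 3106), Ctsg (1231 and 1424), Dach1 (1823 and 2055) and Icam5 (1262 and 1554). They read below them for Igf2 (220 and 209) and Col8a1 (150 and 199). Whether these probe sets bind other transcripts was not tested.

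The largest rises with age were in Psca and Slurp1, members of the Ly6 family of surface and secreted proteins. Psca rose from 51.1 ± 1.30 (n = 2) to 1673 ± 523 (n = 3; 24.4-fold, limma adjusted p = 4.52e-05). Slurp1 rose from 61.6 ± 66.0 to 1269 ± 235 (20.5-fold, limma adjusted p = 0.000887). Ly6g6c, of the same family, rose 3.88-fold (limma adjusted p = 0.00361). Of the 6 genes with the largest rise, the other 4 had P10 indices below 0, so no fold is given. They were Ccr8 (307 ± 165 in the adult and -189 ± 244 at P10, limma adjusted p = 0.000188), Aopep (279 ± 126 and -196.3 ± 39.8, limma adjusted p = 0.0001545), Dnah8 (200.5 ± 70.4 and -222 ± 159, limma adjusted p = 9.03e-05) and Tamm41 (183 ± 129 and -302 ± 8.95, limma adjusted p = 0.00490, 0.0531 without P10 cornea replicate 2). On the tendon arrays their means lay between -2105 and -910.

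The 32 corneal and stratified epithelial genes went both ways, 3 higher and 3 lower (4 and 6 adjusted over the list alone). Their median log2 change was 0.05, or 0.18 relative to all genes (camera in limma, adjusted p = 0.0197; adjusted p = 0.671 with an estimated correlation, 0.233 with quantile normalization and 0.327 without adult cornea replicate 2). Krt12, the cornea-specific keratin, was at 7197 ± 948 in the adult and 6877 ± 617 at P10 (limma adjusted p = 0.952). Krt12 gave the highest index on every cornea array, where saturation could hide a change and was not tested. Aldh3a1 was at 6605 ± 867 and 6603 ± 524 (limma adjusted p = 0.999; log2 -0.01, and 0.14 with trimmed mean scaling), and Tkt was at 4549 ± 124 and 4419 ± 251 (limma adjusted p = 0.974). Another Aldh3a1 probe set read higher in the adult, at 2928.5, 2835.1 and 2957.7, than at P10, at 2048.2 and 1783.2. The lack of a change in Aldh3a1 thus belongs to the first probe set.

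Antigen presentation and interferon response genes had 2 of 15 members higher in the adult and 0 lower (3 and 0 adjusted over the list alone), with a median log2 change of 0.26, or 0.39 relative to all genes (camera in limma, adjusted p = 2.33e-05; adjusted p = 0.231 with an estimated correlation). The members that rose, Psmb8 and Psmb9, encode subunits of the immunoproteasome. Psmb8 went from 90.6 ± 11.9 (n = 2) to 311 ± 90.5 (n = 3; 2.99-fold, limma adjusted p = 0.00598, but 0.0861 without P10 cornea replicate 2). Psmb9 went from 40.5 ± 0.57 to 104 ± 19.8 (2.10-fold, limma adjusted p = 0.0141, but 0.0512 without adult cornea replicate 1, 0.136 without P10 cornea replicate 1 and 0.147 without P10 cornea replicate 2, and 0.0632 in a fit of only the groups compared).

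Markers of other cell types also differed between the ages. Of 5 melanocyte and pigment epithelium genes 3 were lower in the adult, in both adjustments (median log2 -1.18 relative to all genes; camera in limma, adjusted p = 0.00506, 0.0821 without adult cornea replicate 2; adjusted p = 0.368 with an estimated correlation). Pmel, a melanosome protein gene, measured 430 on P10 cornea replicate 1 and 1647 on replicate 2, against 147 ± 31.0 (n = 3) in the adult (5.33-fold, limma adjusted p = 0.0128, 0.0810 in a fit of only the groups compared). Of 8 vascular endothelial genes 1 was lower (4 adjusted over the list alone; camera in limma, adjusted p = 0.0197; adjusted p = 0.302 with an estimated correlation). That list's camera call (limma) was lost without adult cornea replicate 1 (adjusted p = 0.0646), adult cornea replicate 2 (0.0604) or P10 cornea replicate 2 (0.0993), and with no filter on low values (0.0637). Its called gene Cdh5 was at 46.3 ± 11.4 at P10 and 0.69 ± 6.70 in the adult (limma adjusted p = 0.00368, 0.0743 without P10 cornea replicate 2). Of 9 lens crystallins 1 was higher and 2 lower (1 and 3 adjusted over the list alone; camera in limma, adjusted p = 0.440). Cryaa was at 1934 ± 595 in the adult and 2343 ± 1046 at P10 (limma adjusted p = 0.831). Crybb2 was at 1179 ± 304 and 470 ± 125 (2.44-fold higher in the adult, limma adjusted p = 0.0188, but 0.227 without P10 cornea replicate 1, 0.0555 without replicate 2 and 0.0842 in a fit of only the groups compared).

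A few lists passed the test with small shifts. The adipocyte list, with 2 of 10 genes higher (3 higher and 1 lower adjusted over the list alone), tested higher with camera in limma at adjusted p = 0.0455 (adjusted p = 0.368 with an estimated correlation). Its median was -0.03 and its mean 0.12. The adipocyte median turned positive with quantile normalization and trimmed mean scaling (0.15 and 0.07). The camera call in limma was lost in both settings (adjusted p = 0.0714 and 0.0958). The call was also lost with a replicate block (camera in limma, adjusted p = 0.188), with the mean over probe sets (0.0547) and with no filter on low values (0.0593). It was lost without either lens array, adult cornea replicates 1 or 3 or P10 cornea replicate 1 (camera in limma, adjusted p = 0.0511 to 0.184). Mitochondrial respiratory chain genes tested higher with camera in limma (adjusted p = 0.0415, 0.0954 with quantile normalization; adjusted p = 0.714 with an estimated correlation), with a median of 0.05 and a mean of -0.01. Of its 38 genes 1 was called, in both adjustments. This was Cyc1, a subunit of complex III, which was lower in the adult (limma adjusted p = 0.0240) and lost its call without P10 cornea replicates 1 or 2, adult cornea replicate 1 or either tendon array (adjusted p = 0.0529 to 0.182). The 1 of 30 antioxidant and detoxification genes called was higher (1 higher and 1 lower adjusted over the list alone; camera in limma, adjusted p = 0.0197; adjusted p = 0.671 with an estimated correlation). The respiratory chain and antioxidant calls of camera in limma were lost without adult cornea replicate 2 (adjusted p = 0.667 and 0.150) or P10 cornea replicate 2 (0.326 and 0.0664).

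The other 11 lists did not pass the camera test in limma between the ages (adjusted p = 0.129 to 0.992). In limma's test 0 of 26 cell cycle genes passed, with 2 at an unadjusted p under 0.05, and 0 of 8 tendon lineage genes, with 2 at that level (2 lower adjusted over the list alone). Counts were likewise 0 of 6 corneal crystallins and soluble enzymes and 0 of 6 Schwann cell genes, with 0 at that level in both. They were 0 of 17 immediate-early, 0 of 15 glycolysis and 0 of 19 ribosomal protein genes, with 1 each at that level. Lower in the adult were 1 of 9 lens fibre genes, 2 of 33 skeletal muscle genes, 2 of 18 leukocyte genes and 1 of 7 photoreceptor genes (1, 3, 3 and 1 adjusted over the list alone). The medians of the leukocyte, Schwann cell, immediate-early, glycolysis and ribosomal protein lists were below 0 as deposited and above 0 with quantile normalization and trimmed mean scaling, and that of the muscle list with quantile normalization. The camera tests of these lists except muscle were positive while their deposited medians were negative, and the immediate-early mean was 0.01.

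Of 8154 tested probe sets, 57 were higher and 316 lower in the adult than in the P10 cornea by limma's test, 51 and 253 of them by at least 2-fold. The share called higher, 15.3%, was 27.3% with quantile normalization, 26.7% with trimmed mean scaling and 29.0% with median centring, as the median log2 difference of all probe sets moved from -0.13 to 0.03, 0.00 and 0.04. The counts moved to 23 higher and 85 lower without P10 cornea replicate 1 and to 16 and 68 without replicate 2. They were 32 and 162 in a fit of only the groups compared. The count of lower probe sets was 187 without adult cornea replicate 1, the array with the high 3'/5' ratios, 193 without tendon replicate 1 and 196 without tendon replicate 2. Of 50 named genes called here, 22 kept their call in all 9 fits that left out 1 array. Col3a1, Col5a2, Col11a1, Col4a1, Col15a1, Eln, Thbs2, Mfap2, Col8a1, Igf2, Erbb4, Ctsg, Dach1, Icam5, Psca, Slurp1, Ly6g6c and Pmel were among the 22. In fits that left a group with 1 array, that array was assumed to vary like the other groups.

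The comparison of adult cornea with lens set a connective tissue and its residual epithelium against the other transparent tissue of the eye. Most epithelial and soluble enzyme genes were higher in the cornea. Of 32 epithelial genes 27 were higher and 0 lower, in both adjustments, with a median log2 difference of 3.46. Krt12 was at 7197 ± 948 (n = 3) in the cornea and 1681 ± 109 (n = 2) in the lens (4.23-fold, limma adjusted p = 1.53e-05). A saturated index in the cornea would understate the Krt12 folds over lens and tendon. Cldn7, which encodes a tight junction claudin, was at 824 ± 189 and 1.84 ± 7.67 (limma adjusted p = 2.68e-07). Sfn and the hemidesmosomal integrin gene Itgb4 were at 1603 ± 420 and 1029 ± 171 in the cornea and were listed below 0 on both lens arrays (limma adjusted p = 6.75e-07 and 1.09e-07). Of 6 corneal crystallins and soluble enzymes 5 were higher (5 higher and 1 lower adjusted over the list alone), with Aldh3a1 11.03-fold higher (limma adjusted p = 7.12e-07), Gsto1 7.48-fold (limma adjusted p = 9.32e-07) and Tkt 6.82-fold (limma adjusted p = 7.65e-06). The camera tests in limma of both lists passed (adjusted p = 1.78e-11 and 0.0182; adjusted p = 0.189 and 0.451 with an estimated correlation).

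Most collagens were also higher in cornea than in lens. Of 14 collagens 9 were higher and 3 lower, in both adjustments (median log2 1.23; camera in limma, adjusted p = 0.0247; adjusted p = 0.227 with an estimated correlation). Col1a1, a chain of the main stromal collagen, was at 2279 ± 37.8 (n = 3) in the cornea and 41.7 ± 2.65 (n = 2) in the lens (39.8-fold, limma adjusted p = 3.75e-08). Of 7 small leucine-rich proteoglycans 4 were higher and 1 lower, in both adjustments (camera in limma, adjusted p = 0.129). Lum was 17.4-fold higher (limma adjusted p = 1.55e-06), Dcn 13.3-fold (limma adjusted p = 4.16e-07) and Kera was at 213 ± 87.6 and 11.8 ± 5.77 (limma adjusted p = 2.04e-05), while Ogn was at 93.3 ± 22.6 in the cornea and 994 ± 315 in the lens (limma adjusted p = 7.49e-06). Fmod did not pass (136 ± 37.2 and 130 ± 120, limma adjusted p = 0.584). Tgfbi, an abundant corneal matrix protein gene, was 23.8-fold higher in the cornea (limma adjusted p = 1.59e-07).

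Most lens genes were higher in the lens. All 9 measured lens crystallins were lower in the cornea, in both adjustments (median log2 -2.38). All lay in the top 1% of the lens arrays, where a saturated index would understate these differences. Cryaa was at 6818 ± 584 (n = 2) in the lens and 1934 ± 595 (n = 3) in the cornea (limma adjusted p = 0.00146). Crybb2 was at 6875 ± 349 and 1179 ± 304 (limma adjusted p = 1.95e-05) and Crygc at 6989 ± 711 and 783 ± 174 (limma adjusted p = 4.75e-06). Of 9 lens fibre and lens epithelium genes 6 were higher in the lens and 3 in the cornea, in both adjustments (median log2 -3.33), and Pax6, which the cornea also expresses, was 1 of the 3. Bfsp1 and Mip, genes of the fibre cell cytoskeleton and membrane, were at 3516 ± 305 and 1859 ± 83.6 in the lens and at 68.9 ± 9.45 and 33.2 ± 5.39 in the cornea (limma adjusted p = 1.09e-07 and 2.27e-07). Both lists passed the camera test in limma (adjusted p = 7.35e-06 and 0.0265; adjusted p = 0.368 for each with an estimated correlation). Col4a1 and Col4a5, basement membrane collagens, were higher in the lens, at 2066 ± 591 and 443 ± 101 (limma adjusted p = 1.32e-06 and 1.46e-06). The 6 largest differences in favour of the lens were in Relb (1831 ± 194 in the lens, listed below 0 on all adult corneas, limma adjusted p = 4.56e-07), Mgat3, Pgam2, Tpgs1, Svs5 and Gm12219. These others had lens means from 900.5 to 1534, cornea means from -84.6 to 10.8 and limma adjusted p from 1.09e-07 to 3.47e-05. Svs5 also belongs to the organ-restricted genes read below for binding of other transcripts in lens. Hmox1, a heme oxygenase gene, was 12.8-fold higher there (limma adjusted p = 1.02e-06).

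Further groups separated cornea from lens. Antigen presentation and interferon response genes were higher in the cornea in 12 of 15 cases and lower in 1, in both adjustments, with Psmb8 at 311 ± 90.5 (n = 3) and below 0 on both lens arrays (limma adjusted p = 7.22e-07) and H2-K1 9.07-fold higher (limma adjusted p = 1.58e-05). Other probe sets of H2-K1 were called in the opposite direction. Of 26 cell cycle genes 15 were higher and 4 lower (17 and 4 adjusted over the list alone), with Lig1 4.94-fold higher (limma adjusted p = 6.78e-05) and Rrm2 6.34-fold lower (limma adjusted p = 5.43e-06). Of 17 immediate-early genes 10 were higher and 0 lower (11 and 1 adjusted over the list alone), with Klf4 14.4-fold higher (limma adjusted p = 5.63e-07). Klf4 also belongs to the epithelial list. The camera tests in limma of these 3 lists gave adjusted p = 0.00185, 0.0183 and 0.0193 (adjusted p = 0.368, 0.5004 and 0.368 with an estimated correlation). Of 7 photoreceptor genes 4 were lower in the cornea, in both adjustments (camera in limma, adjusted p = 0.0455; adjusted p = 0.671 with an estimated correlation). This camera call (limma) was lost without lens replicate 1 (adjusted p = 0.0909), adult cornea replicate 1 (0.0777) or replicate 2 (0.0683) and with quantile normalization (0.0596). The photoreceptor gene Sag measured 240, 346 and 1204 on the adult corneas and 1015 and 533 on the lens arrays.

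The other 16 lists did not pass the camera test in limma between cornea and lens (adjusted p = 0.132 to 0.981). Counts higher and lower in the cornea were 3 and 5 of 12 for collagen processing, 8 and 6 of 18 for basement membranes, 8 and 5 of 20 for matricellular genes, 3 and 1 of 8 for tendon genes, 5 and 1 of 10 for adipocytes and 5 and 3 of 18 for leukocytes, the same adjusted over the list alone. They were also the same in that adjustment for melanocytes (1 and 1 of 5), vascular endothelium (0 and 1 of 8), Schwann cells (1 and 3 of 6), the respiratory chain (4 and 8 of 38), glycolysis (4 and 7 of 15) and growth factor signalling (9 and 13 of 30). Counts differed for corneal endothelium (1 and 2 of 4; 2 and 2 adjusted over the list alone), muscle (4 and 11 of 33; 3 and 11), antioxidant genes (14 and 9 of 30; 15 and 10) and ribosomal proteins (6 and 0 of 19; 3 and 0). Basement membrane, leukocyte and vascular lists had positive medians (0.29, 0.08 and 0.09) and negative means (-0.20, -0.10 and -0.13), and the signalling list a median of -0.29 and a mean of 0.03. The camera test took the sign of the mean for the basement membrane and vascular lists and that of the median for the leukocyte and signalling lists.

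By limma's test 2219 of 8154 probe sets were higher and 1956 lower in adult cornea than in lens, 1367 and 1349 of them by at least 2-fold. Without lens replicate 2 the first count was 1399, and without adult cornea replicate 1 the counts were 1887 and 1794. Of 84 named genes called here, 77 kept their call in all 9 fits that left out 1 array. In 94 of the 318 genes with several called probe sets (29.6%), those probe sets went in opposite directions between cornea and lens, so a call here belongs to its probe set rather than to the gene.

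The comparison of adult cornea with tendon set a pair of collagen-rich connective tissues against each other. Tendon and general fibrous matrix genes were lower in the cornea. Of 8 tendon lineage and matrix genes 7 were lower and 0 higher, in both adjustments (median log2 -2.68), and the list shares Fmod and Chad with the proteoglycan list. Fmod, which encodes fibromodulin, was at 136 ± 37.2 (n = 3) in the cornea and 5899 ± 627 (n = 2) in the tendon (39.7-fold, limma adjusted p = 1.22e-05). Chad, which encodes chondroadherin, was at 73.9 ± 16.7 and 5428 ± 267 (61.3-fold, limma adjusted p = 3.38e-08), and Cilp2 was at 130 ± 12.0 and 5427 ± 426 (37.2-fold, limma adjusted p = 2.95e-08). Of 7 small leucine-rich proteoglycans 5 were lower and 0 higher, in both adjustments. Dcn was 2.47-fold lower (limma adjusted p = 0.000420), while Lum (845 ± 286 and 650 ± 26.2, limma adjusted p = 0.403) and Kera (213 ± 87.6 and 224 ± 16.6, limma adjusted p = 0.759) did not pass the test. Of 14 collagens 10 were lower and 1 higher (11 and 1 adjusted over the list alone), with Col3a1 31.5-fold lower (limma adjusted p = 6.30e-07). Col11a2 was at 621 ± 71.4 in the cornea and at -44.7 and 121 on the tendon arrays (limma adjusted p = 0.00146).

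Matrix processing genes followed the same direction. Of 12 collagen processing genes 7 were lower, in both adjustments, with Lox 23.0-fold lower (limma adjusted p = 4.92e-06). Of 20 matricellular genes 15 were lower and 1 higher (15 and 3 adjusted over the list alone), with Ccn2, a connective tissue growth factor gene, 17.1-fold lower (limma adjusted p = 1.84e-06). The tendon, proteoglycan, collagen, processing and matricellular lists passed the camera test in limma (adjusted p = 2.34e-06, 0.00103, 0.000208, 0.000714 and 1.75e-05). With an estimated correlation they had adjusted p = 0.159, 0.227, 0.159, 0.227 and 0.189. Igfbp6, a binding protein for insulin-like growth factors, was at 3756 ± 95.6 (n = 2) in the tendon and 45.1 ± 15.7 (n = 3) in the cornea (63.1-fold, limma adjusted p = 9.00e-08).

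Epithelial and soluble enzyme genes were higher in the cornea. Of 32 epithelial genes 27 were higher and 2 lower (28 and 2 adjusted over the list alone; median log2 3.25), with Krt12 21.3-fold higher (limma adjusted p = 1.25e-07) and Dsc2, a desmosomal cadherin gene, at 860 ± 283 (n = 3) in the cornea and 5.09 ± 0.08 (n = 2) in the tendon (limma adjusted p = 2.68e-07). Of 6 soluble enzyme genes 4 were higher and 1 lower, in both adjustments. Aldh3a1 was at 6605 ± 867 (n = 3) in the cornea and listed below 0 on both tendon arrays (limma adjusted p = 6.26e-09). Gsto1 was 37.5-fold higher (limma adjusted p = 2.95e-08) and Tkt 32.6-fold higher (limma adjusted p = 1.63e-07). Lens crystallins were higher in cornea than in tendon for 8 of 9 genes and lower for 1, in both adjustments (median log2 5.09), with Cryaa at 1934 ± 595 and 21.9 ± 13.8 (limma adjusted p = 9.77e-07). Crybb2 was at 1179 ± 304 in the cornea and below 0 on both tendon arrays (limma adjusted p = 9.00e-08). Krt6a (3673 ± 648), Plet1 (1961 ± 532), Cryba1 (1454 ± 300) and Gsta4 (3725 ± 151) were also among the 6 genes with the largest difference in favour of the cornea (limma adjusted p = 2.95e-08 to 4.65e-07). Cell cycle genes were higher for 12 of 26 and lower for 1 (13 and 1 adjusted over the list alone), with Mki67, a proliferation marker, 5.33-fold higher (limma adjusted p = 0.000158). These 4 lists passed the camera test in limma (adjusted p = 4.91e-16, 0.00295, 4.83e-08 and 1.54e-05; adjusted p = 0.159, 0.368, 0.284 and 0.231 with an estimated correlation).

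Markers of cell types other than tendon fibroblasts were high on the tendon arrays. Of 33 skeletal muscle genes 26 were lower in the cornea and 1 higher (26 and 2 adjusted over the list alone; median log2 -5.18), with Myh4, a fast myosin heavy chain, at 6159 ± 819 (n = 2) in the tendon and 4.91 ± 2.58 (n = 3) in the cornea (limma adjusted p = 2.52e-08). Tnnt3, a fast troponin gene, was at 6259 ± 481 and 17.5 ± 3.71 (limma adjusted p = 6.26e-09). Of 10 adipocyte genes 8 were lower and 1 higher (9 and 1 adjusted over the list alone), with Fabp4 at 16.4 ± 5.70 in the cornea and 1950 ± 300 in the tendon (limma adjusted p = 3.54e-08). Leukocyte genes were lower for 9 of 18, in both adjustments, with Lyz2 at 10.3 ± 5.79 in the cornea and 313 ± 39.4 in the tendon (limma adjusted p = 1.30e-06). Vascular endothelial genes were lower for 5 of 8 (7 adjusted over the list alone), with Cd34 5.99-fold lower (limma adjusted p = 8.54e-06). Respiratory chain genes were lower in the cornea for 26 of 38 and higher for 1 (31 and 1 adjusted over the list alone), with the muscle isoform Cox6a2 at 2.04 ± 2.49 in the cornea and 3508 ± 142 in the tendon (limma adjusted p = 1.81e-08). Glycolysis genes were lower for 10 of 15, with 4 higher (10 and 5 adjusted over the list alone) and the muscle enolase Eno3 58.2-fold lower (limma adjusted p = 1.35e-07). These 6 lists passed the camera test in limma (adjusted p = 1.46e-16, 2.34e-06, 0.000208, 0.00106, 1.93e-08 and 0.0197). With an estimated correlation they had adjusted p = 0.139, 0.159, 0.159, 0.189, 0.368 and 0.671.

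Photoreceptor genes were higher in cornea than in tendon for 5 of 7 (6 adjusted over the list alone; camera in limma, adjusted p = 0.00185; adjusted p = 0.451 with an estimated correlation), with Sag at 597 ± 529 (n = 3) in the cornea and -1.73 ± 5.01 (n = 2) in the tendon (limma adjusted p = 9.18e-05). The other 10 lists did not pass the camera test in limma (adjusted p = 0.0777 to 0.782). Counts higher and lower in the cornea were 4 and 8 of 18 for basement membranes (4 and 9 adjusted over the list alone), 1 and 1 of 4 for corneal endothelium (1 and 2), 8 and 1 of 15 for antigen presentation (9 and 2), 5 and 1 of 19 for ribosomal proteins (4 and 1) and 6 and 15 of 30 for growth factor signalling (6 and 16). They were 2 and 0 of 9 for lens fibre genes, 0 and 2 of 6 for Schwann cells, 9 and 7 of 30 for antioxidant genes, 3 and 5 of 17 for immediate-early genes and 0 and 0 of 5 for melanocytes, the same adjusted over the list alone. In limma's test 1 melanocyte gene reached an unadjusted p under 0.05. The lens fibre list had a median of -0.13, a mean of 0.55 and a positive test.

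**Figure D3:**
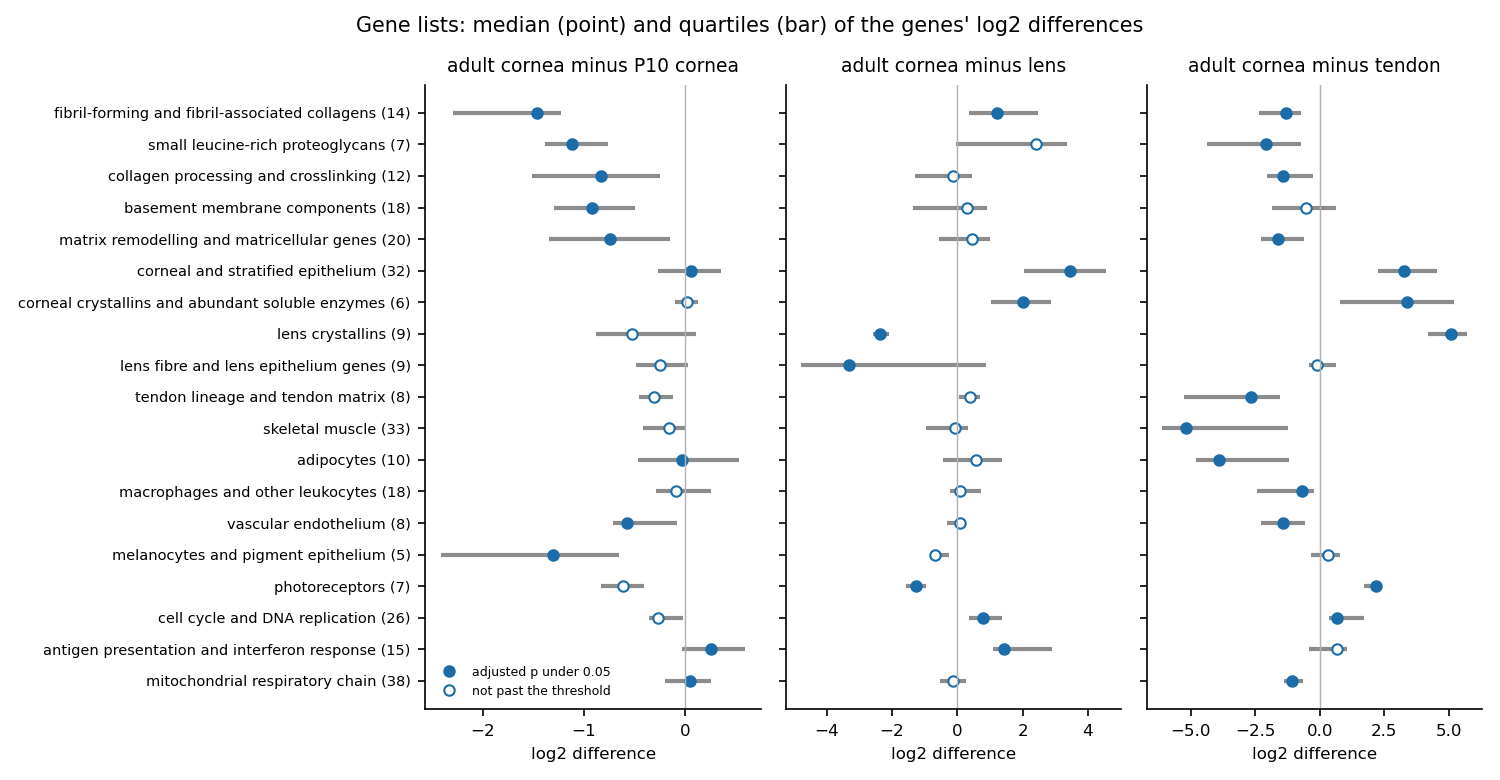
Median log2 difference (point, horizontal axis) and quartiles (bar) of 19 gene lists in the 3 comparisons with adult cornea, with the number of measured genes in parentheses; filled points passed the camera test at the preset correlation. Collagens lie below 0 against P10 cornea (-1.46) and tendon (-1.33) and above 0 against lens (1.23), while the adipocyte and leukocyte medians against P10 cornea change sign with quantile normalization and trimmed mean scaling, as the muscle median does with quantile normalization.

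By limma's test 1316 of 8154 probe sets were higher and 1540 lower in adult cornea than in tendon, 832 and 1026 of them by at least 2-fold. The counts were 657 and 1010 without tendon replicate 1 and 785 and 985 without tendon replicate 2, and 1042 and 1340 without adult cornea replicate 1. Of 75 named genes called here, 68 kept their call in all 9 fits that left out 1 array.

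The P10 cornea was compared with the same adult lens and tendon arrays, so age and tissue differ together in these comparisons. The values that follow for Col1a1, Col3a1, Col5a2 and Igf2 were chosen after they were seen. Against tendon, Col1a1 was at 6452 ± 445 (n = 2) in the P10 cornea and 8527 ± 561 (n = 2) in the tendon (limma adjusted p = 0.0819). Col5a2 was at 1643 ± 273 and 1426 ± 6.50 (limma adjusted p = 0.702), while Col3a1 was 2.56-fold lower (limma adjusted p = 0.00994). Lum was 2.70-fold higher in P10 cornea than in tendon (limma adjusted p = 0.00570), Dcn 1.59-fold lower (limma adjusted p = 0.0368), Fmod 11.8-fold lower (limma adjusted p = 0.000596) and Kera did not pass (limma adjusted p = 0.110). Igf2 was 4.83-fold higher than in tendon (limma adjusted p = 0.000252) and 23.1-fold higher than in lens (limma adjusted p = 1.96e-06). Against lens, Col1a1 was 112-fold higher (limma adjusted p = 8.00e-09), Lum 37.7-fold (limma adjusted p = 1.27e-06) and Aldh3a1 11.1-fold (limma adjusted p = 1.88e-06), and Crybb2 was at 470 ± 125 and 6875 ± 349 (limma adjusted p = 3.42e-06).

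In total 2578 probe sets were higher and 1578 lower in P10 cornea than in lens, and 1277 higher and 897 lower than in tendon (limma). The share higher was 62.0% against lens and 58.7% against tendon, and 50.6% and 48.5% with median centring, as the median log2 difference of all probe sets moved from 0.25 to 0.04 and from 0.13 to 0.00. Against lens the higher count was 1650 without lens replicate 2 and 1622 without P10 cornea replicate 1, and 1702 with the filter at percentile 75. Against tendon the counts were 551 and 511 without tendon replicate 1, 688 and 502 without tendon replicate 2, 568 and 551 without P10 cornea replicate 1 and 744 and 509 without P10 cornea replicate 2. They were 2333 and 1499 in a fit of only the groups compared.

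Genes shared by the cornea at both ages were those that passed limma's test by at least 2-fold in the same direction in all 4 comparisons with lens and tendon, 398 probe sets higher and 87 lower. With a pseudocount of 64 the counts were 250.0 and 48. The 398 were led by Aldh3a1, Adh1, Krt6a, Col17a1, Sfn, Pkp1, Igfbp2, Cldn7 and a pair of probe sets with no single gene symbol. Adh1, an alcohol dehydrogenase gene, was at 1683 ± 127 (n = 3) in adult and 1672 ± 90.0 (n = 2) in P10 cornea, against 10.9 ± 35.2 in lens and 7.98 ± 2.30 in tendon. Col17a1, a hemidesmosomal collagen gene, was at 1882 ± 359 and 1980 ± 334, against 35.1 ± 7.33 and 51.5 ± 37.2, and Igfbp2 at 1176 ± 201 and 1884 ± 152, against 51.9 ± 32.6 and 26.6 ± 1.62. Among the 322 genes of the higher set, 25 of the 32 epithelial genes occurred (1.69 expected of 6109 genes; Fisher's exact test, adjusted p = 5.63e-25). So did 8 of 26 cell cycle genes (adjusted p = 0.000962), 3 of 6 corneal enzyme genes (adjusted p = 0.0335) and 6 of 30 antioxidant genes (adjusted p = 0.0431) in the same exact test over both sets and 26 lists.

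The 87 lower probe sets were led by Pgam2, Cilp2, Fxyd1, S100a4, Selenow, Adk, Casq1, Eno3, Chpt1 and a probe set with no single gene symbol. The probe sets of Cilp2 were called in opposite directions between cornea and lens. S100a4, which encodes a calcium-binding protein, was at 173 ± 19.7 (n = 3) in adult and 173 ± 0.41 (n = 2) in P10 cornea, against 1894 ± 244 in lens and 3106 ± 413 in tendon, and Fxyd1, a regulator of the sodium pump, at 57.5 ± 19.9 and 56.5 ± 21.5 against 941 ± 143 and 1418 ± 116. Of the 68 genes in this set, 4 were among the 33 muscle genes (Fisher's exact test, adjusted p = 0.00781). If the comparisons with lens and with tendon were independent, 95.5 higher and 75.9 lower probe sets would be shared, against 398 and 87 observed. The excess thus lay mainly in the higher set, and the lower count was close to that under independence. In 20 simulations without differences 0 were shared, as such strict calls give where nothing differs, so this 0 is no baseline for the excess. All 4 comparisons share their cornea arrays, so part of the excess may come from the common arrays. Part may also come from a batch, since the cornea arrays served an earlier study, and batch and tissue cannot be told apart.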

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

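The tests of probe sets with an index below 0 were chosen after the result was seen. The limma comparisons used here were planned. Some genes lay on opposite sides of another tissue at the 2 ages of the cornea: the adult cornea was called on one side of the tissue and the P10 cornea on the other. A limma call between the ages, as adult minus P10 on the log2 scale, was also required. The adjusted p-values given for these genes therefore restate the choice and are no further test.

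Against both lens and tendon, Peg3, an imprinted gene, and Rest, a repressor of neuronal genes, were lower in adult cornea and higher in P10 cornea. Peg3 was at 28.2 in the adult and 238 at P10, against 79.0 in lens and 115 in tendon (log2 -2.53 ± 0.21 SE, limma adjusted p = 0.000242). Rest was at 25.7 and 126, against 51.2 and 60.7 (log2 -1.78 ± 0.20 SE, limma adjusted p = 0.00101). Against lens alone, the same held for Ddr2, a collagen receptor (log2 -2.32, limma adjusted p = 0.00602), Pzp (log2 -1.53, limma adjusted p = 0.00490) and Ramp2 (log2 -1.515, limma adjusted p = 0.00368). It also held for 3 probe sets without a gene symbol (log2 -2.11, -2.76 and -1.705). Against tendon alone, it held for Col8a1 (log2 -2.41, limma adjusted p = 0.000216), the fibril-associated collagen Col14a1 (log2 -2.40, limma adjusted p = 0.00230) and the histone demethylase Kdm6a (log2 -1.13, limma adjusted p = 0.00550). In 3 further genes the mean at 1 age was below 0, so the pseudocount sets the log2 difference and it is no measure of size. Ctsg was at -26.5 in the adult and 811 at P10, against 184 in lens (log2 -5.07). Adcyap1r1 was at -12.85 and 47.2, against 12.1 in tendon (log2 -1.95). Tamm41 was at 183 in the adult and -302 at P10, against 49.1 in lens (log2 3.37), and its call was lost without P10 cornea replicate 2 (limma adjusted p = 0.0531).

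Tamm41 belongs to 5 probe sets called higher in adult than in P10 cornea that had a P10 mean below 0 and a value below -100, with Ccr8, Aopep, Dnah8 and Gm29722. The median of their P10 means was -196.3, but they were chosen for a P10 mean below 0, so this value does not decide whether less of the gene's own transcript at P10 is the cause. In all 5 of them the tendon mean lay below the P10 mean, with a median of -1422, but Gm29722 lay below -100 only on tendon arrays. The other 4 also did so on a P10 array. Of 17 further probe sets with a P10 mean below 0 and a P10 array below -100, 12 had a tendon mean below the P10 mean (exact p = 0.532), and 4 probe sets are too few to set these genes apart. A transcript abundant in tendon and P10 cornea that binds the mismatch probes more than the perfect match probes therefore cannot be told apart from a difference in the genes' own transcripts between the ages.

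Of 33 bacterial and phage control probe sets, which take no part in the comparisons, 4 read at least 2 times as high on both lens arrays as on any other array, and at or above the lens arrays' medians. The lower of the lens readings was 272.1 for a BioB antisense probe set, against at most 107.4 elsewhere. It was 175.5 for a DapX probe set (at most 49.2 elsewhere), 108.3 for a LysX probe set (30.7) and 314.8 for a TrpnX probe set (30.6). These differences were not tested.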

How the results depend on the processing

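Dropping probe sets with a value below -100 was chosen after the data were seen, and the other alternatives were planned. Counts are given as higher and lower, by limma unless another test is named, and the cause of each change was not tested except where the construction shows it. For the named genes 4386 results under the alternatives kept their direction and side of the threshold, 172 became weaker, 9 stronger and 0 reversed, and for the lists 1146, 69, 32 and 1. The 1 that reversed was the respiratory chain between adult and P10 cornea, higher by camera and lower by fry at the same median of 0.0474 (fry in limma, adjusted p = 0.990). Of 78 list tests camera called 39 at the preset correlation and 1 with an estimated correlation. Fry called 50, as 5 of camera's 39 calls were lost, 1 was lost with the opposite direction and 17 were added.

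Settings moved some counts by more than 1.5 times. With a pseudocount of 64 the cornea-shared counts were 250.0 and 48. With the filter at percentile 75, which tests fewer probe sets, 1702 were higher in P10 cornea than in lens. Between adult and P10 cornea 91 were higher with quantile normalization, 86 with trimmed mean scaling, and 196 were lower with median centring. Fits of only the groups compared, which change the estimate of spread, gave 32 and 162 for adult against P10 cornea and 2333 and 1499 for P10 cornea against tendon.

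The 2-group test of the series' methods, with its fold and difference limits, gave 27 and 114 for adult against P10 cornea, 680.0 and 573 for adult cornea against lens, 441 and 577 against tendon, 605 and 431 for P10 cornea against lens, 280.0 and 350.0 against tendon, and 82 and 16 shared. The 2-group test after Benjamini-Hochberg, without those fold and difference limits, gave 0 and 0 for adult against P10 cornea. Limma gave 57 and 316 there, and 1283 at an unadjusted p under 0.05. The other counts of the 2-group test, in the same order, were 19 and 76, 20 and 92, 2 and 1, 0 and 0, and 0 and 0 shared. This test takes its spread from 2 or 3 arrays per group.

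Leaving out 1 array, the counts ranged from 16 to 84 higher and 68 to 342 lower for adult against P10 cornea, 1399 to 2332 and 1531 to 2117 for adult cornea against lens, and 657 to 1531 and 985 to 1679 against tendon. They ranged from 1622 to 2795 and 1155 to 1726 for P10 cornea against lens, 551 to 1567 and 502 to 1036 against tendon, 285 to 428 and 66 to 90 for the shared sets, and 33 to 41 for the list tests. A group left with 1 array was assumed to vary like the others.

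Without probe sets with a value below -100 the counts were 49 and 316, 2174 and 1950, 1302 and 1525, 2526 and 1560, 1280 and 896, and 392 and 84 shared. With a replicate block they were 79 and 302, 2246 and 2045, 1495 and 1576, 2714 and 1666, 1493 and 981, and 428 and 91 shared, with 39 list tests. The arrays share only a number: deviations of same-numbered arrays correlated across genes, which are not independent replicates, at r = -0.363 to 0.201, with 4 of 12 pairs above 0.1. In a group of 2 arrays the deviations are exact opposites, so some pairs repeat and the 12 are not separate readings. The highest correlation of any pair, r = 0.509, was between adult cornea replicate 3 and P10 cornea replicate 2, which have different numbers. Signal over background limits genes near an index of 0, where the pseudocount sets the fold.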

Other observations

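The test of lens carryover was chosen after the result was seen, and the tests of opposite probe sets were planned. Most lens crystallins read higher on the cornea arrays than on the tendon arrays, except Cryab, at 232 in adult and 217 in P10 cornea and 364 in tendon. Cryaa measured 1280, 2443 and 2078 on the adult corneas and 1603 and 3082 on the P10 corneas, against 21.9 ± 13.8 (n = 2) on tendon. All 9 crystallins were higher on P10 cornea replicate 2 than on replicate 1. Sag, the rod arrestin gene, measured 571 and 922 on the P10 corneas.

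The median crystallin reached 18.8% of its lens value in adult cornea, after tendon was subtracted, from -4.23% for Cryab to 28.0% for Cryaa. The 6 lens fibre genes lower in cornea than in lens reached a median of 0.148%. Pitx3 was at 23.5%, Mip at 1.09%, Bfsp1 at 0.696%, Gja3 at -0.40%, Prox1 at -3.92% and Hsf4 at -4.60%. In P10 cornea the crystallins reached from -4.71% for Cryab to 58.2% for Cryge. There Pitx3 was at 12.5%, Bfsp1 at 2.68%, Mip at 2.54%, Prox1 at 0.692%, Gja3 at 0.308% and Hsf4 at -5.15%. All 9 crystallins lay in the top 1% of the lens arrays, where a saturated index would raise their percentage, so lens tissue carried over into the cornea preparations cannot be told apart from other sources. Expression by corneal cells may also account for the crystallins and was not tested.

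In 94 genes with several called probe sets these went in opposite directions between adult cornea and lens, 29.6% of 318, against 25 of 216 between adult cornea and tendon and 87 of 314 (27.7%) between lens and tendon. Of the genes with opposite calls 62.8% had a called probe set of a less specific class. Of the genes called in 1 direction 68.8% did (Fisher's exact test, p = 0.3). Genes with opposite calls thus did not hold such probe sets more often. From a share of 68.8% the rise planned as support could not be reached, so this test does not decide whether those classes are a cause. Without adult cornea replicate 1 the share was 28.0%, which argues against the loss of 5' RNA on that array as the whole cause. Abundant lens transcripts of other genes may bind such probe sets: 21.7% of 69 probe sets of organ-restricted genes reached 200 in lens and 13.0% in adult cornea (exact sign test, p = 0.109), too few to decide. In tendon 23.2% did, and over all probe sets the shares were 20.9% in lens, 20.6% in adult cornea and 21.0% in tendon. Differences between transcript forms of the tissues stay open and were not tested.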
